A study of Mus musculus with 6 samples.

How the data were processed

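BrITL labels DNA ends with a biotinylated nucleotide, pulls the labelled DNA down with streptavidin and sequences it, so that reads gather where DNA was broken. The 6 samples were mouse embryonic fibroblasts heterozygous for Atr, immortalised by passage and expressing Bcl-xL, per the labels. Cells had 18 h of vehicle (DMSO) or 18 h of 1 µM ATR-45, an inhibitor of the replication checkpoint kinase ATR, with 0.2 µM aphidicolin, an inhibitor of DNA polymerases. Each condition had 2 pull-down samples and 1 input sample.

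The deposited data used here were 2 peak lists, 1 per condition. The peak names state that all pull-downs of a condition were set against all its inputs, so each list is pooled and holds no value per sample. There was therefore no replicate error, and tests of peak positions compare these 2 lists, not the conditions. The submitters' processing notes name the genome build mm10 and the tools bcl2fastq 2.17.1.14, STAR 2.5.2a, SAMtools 0.1.19, Picard 1.141 and MACS2 2.1.0, without their roles or settings. The rule by which peaks entered the lists is not given in the sources used here. Each peak name ends in a number that rises along the genome with gaps, up to 64322 (DMSO) and 5400 (treated), so the numbers a region or chromosome spans were read as a count of calls before that rule. Each peak carries a deposited score, which is the whole part of a multiple of its −log10 q. It also carries a fold enrichment at the summit, a ratio computed by the authors' caller, and −log10 p and −log10 q values from the authors' caller. These values are the authors' own. They were used to describe, rank or filter peaks within a list and, as set out below, to recover the coverage behind each peak, and no fold of one list was set against a fold of the other as a change.

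Gene positions came from a RefSeq gene table of the assembly GRCm38.p6, the same assembly as mm10, with 49943 genes on 21 chromosomes, of which 21887 are protein-coding. The table gives gene starts and ends without strand or exons. The planned promoter and exon classes were therefore replaced by summits within 1 kb of either end of a protein-coding gene and summits inside a gene body, and nearest transcription starts by nearest gene ends. No genome sequence was used here, so the planned tests of tandem repeats and other sequence features were not run.

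Overlap of at least 1 bp, gene position, clustering and gene lists were set against 1000 random placements of the peaks. Placements kept peak length and chromosome and lay between the lowest and highest coordinate seen on the chromosome in either list. In each placement positions were redrawn at random, which is what permutation of positions means below. These tests were two-sided, and 0.002 is the smallest p they can give. Overlaps were computed with interval code written for this work in place of the planned tool. Peaks per chromosome were set against 100000 multinomial draws by length, taken as the highest coordinate seen, with Benjamini-Hochberg adjustment per list. The count of any chromosome in such draws is binomial. The smallest p of these draws and of the permutation tests with 100000 resamples is 2e-05. Classes of peaks were compared with two-sided Fisher's exact tests, adjusted over 10 comparisons. Intervals of shares are exact Clopper-Pearson intervals at 95% and cover counting error only. Calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3.

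The files hold no read totals. The caller's formulas (fold as pileup plus 1 over background plus 1, p as a Poisson tail) were inverted for each peak. This gave the pull-down coverage at its summit and the background term, which is called input coverage below. The background term was not let below the list's genome background, where 69.3% of DMSO and 41.8% of treated peaks lay. It is therefore not a direct measure of input at the summit. A solution was accepted where the pull-down coverage lay within 0.02 of a whole multiple of the list's scaling step, which held for 100% of peaks in both lists. On 300 simulated peaks per list, 100% were solved and 100% of these were right. Simulated input coverage was at the background or a whole number above it. In the data 59.4% (DMSO) and 49.0% (treated) of values above the background were whole. Values that are not whole, or as high as the 37 fragments reached in the region of chromosome 15 described below, were not simulated. On simulated lists of 491 peaks with planted overlaps of 5%, 20% and 40%, the placement test gave excesses of 5.26%, 19.8% and 39.7%. Of 100 simulated lists without overlap, 0% had p under 0.05. These lists were drawn by the same random placement that the test uses, so a low rate was built in. They lacked the clustering of the real peaks, for which the rate was not simulated.

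The 7 gene lists were fixed before the data were examined. Of the names written, 30 of 32 common fragile site genes, 33 of 33 genes of break clusters in neural progenitors, 19 of 20 early replicating fragile site genes, 26 of 26 ATR and replication fork genes, 26 of 28 fibroblast genes and 23 of 23 p53 response genes matched the table. Histone genes were taken by a symbol pattern, which gave 97 genes and takes in variant histones. H13, which the pattern matched and which is not a histone gene, was left out after it was seen. The named peaks are the 10 of highest fold among treated peaks that overlap no DMSO peak, 5 among treated peaks that overlap one, and 8 among DMSO peaks that overlap no treated peak. Members of a fixed list whose body holds a treated summit and genes with 3 or more treated summits were also named. Peaks at Myc, Pvt1, Pcna, Pim1 and the strongest peaks of the whole DMSO list were chosen after their values were seen. The region of chromosome 15 described below was found as a run of at least 5 neighbouring bins of 100 kb with at least 5 DMSO peaks each, and this definition, the comparisons without it, the tests of genes with a summit at an end and the tests of peak pairs were added after seeing the data. Alternatives fixed beforehand were a stricter −log10 q of 5, peaks at or above the median fold of their list, merged entries, other definitions of overlap, neighbour and gene end, placement anywhere and autosomes alone.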

Results

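DNA breaks were mapped by BrITL, which sequences biotin-labelled DNA ends, in mouse embryonic fibroblasts given vehicle or an ATR inhibitor with aphidicolin (called treated below). Each condition had 2 pull-down samples and 1 input sample, and the files gave 1 pooled peak list per condition, so no value had a replicate error. The question was where in the genome ends gathered when replication was slowed without ATR. The DMSO list held 6444 peaks with a median width of 2855 bp, covering 19.5 Mb. The treated list held 491 peaks with a median width of 454 bp, covering 0.258 Mb. The authors' fold enrichment ran from 2.80 to 33.8 in the DMSO list and from 2.07 to 14.2 in the treated list. The lowest −log10 q was 18.5 in the DMSO list and 3.38 in the treated list, so the lists did not share a q threshold. Input coverage recovered from the caller's values had a genome background of 2.32 fragments (DMSO) and 2.26 fragments (treated). The pull-down background was 2.88 and 5.14 fragments, and every peak of either list had at least 35 pull-down fragments at its summit.

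Treated and DMSO peaks shared many positions. Of 491 treated peaks, 200 (40.7%, interval 36.4 to 45.2%) overlapped a DMSO peak, against 1.22% of randomly placed peaks (permutation of positions, p = 0.002, the smallest the placements can give). Placed within 1 Mb of their own positions, 6.72% overlapped. The shared peaks of highest fold in the treated list lay at gene ends. They were at 9230110K08Rik beside Camta1, a calmodulin-binding transcription factor gene (fold 7.07), at the histone gene H2ac19 (7.05), in Gt(ROSA)26Sor, a non-coding locus widely used for transgenes, beside Setd5 (7.05), beside H2az1, a variant histone gene (6.65), and in Zfp91 (6.51). Gt(ROSA)26Sor (fold 33.8, chromosome 6, 113074301 to 113079450) and H2ac19 (fold 32.8, chromosome 3, 96239555 to 96239741) also held the DMSO peaks of highest fold in their list, followed by Sp1 (31.4), Tnrc18 (29.99) and Zfp36l2, a regulator of mRNA decay (28.2). The DMSO peaks that met a treated peak had a median fold of 18.0 (n = 187), against 10.99 for the others (n = 6257, permutation test, two-sided p = 2e-05, the smallest it can give). Outside a dense region of chromosome 15 described below, 10.95% of the DMSO peaks in the group with the highest of 5 ranges of fold met a treated peak (interval 9.23 to 12.9%). In the other groups the share ran from 0.253% to 1.09%.

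**Figure D1:**
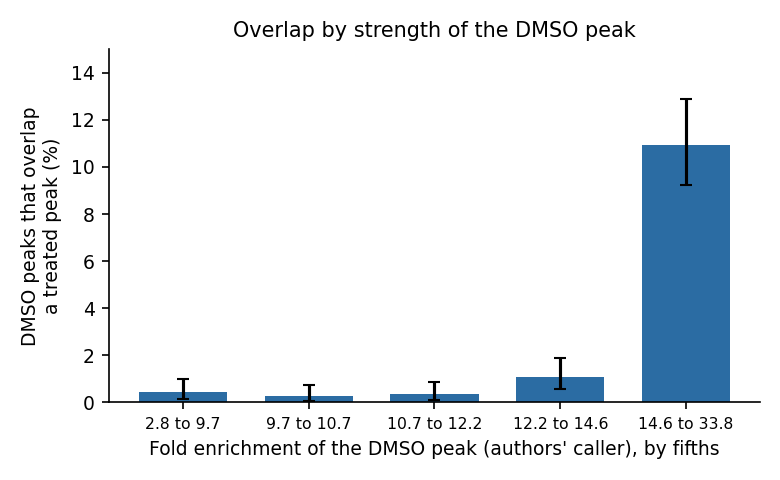
Share of DMSO peaks that overlap a treated peak (%, y axis) in 5 groups of equal size by the authors' fold enrichment (x axis), outside the dense region of chromosome 15, with exact 95% intervals. The share is 10.95% in the group of highest fold and at most 1.09% in the others.

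Most DMSO peaks lay at the ends of genes. Summits within 1 kb of an end of a protein-coding gene made up 57.2% of the DMSO list (3686 peaks), against 3.27% placed, and 26.9% of the treated list (132 peaks), against 3.09% placed (permutation of positions, p = 0.002 for both). The difference between the lists had an odds ratio of 0.275 (Fisher's exact test, adjusted p = 1.17e-38). This p-value is too small, since it counts neighbouring peaks as independent. The lists were also cut at unlike −log10 q, and the share moved with peak strength. Outside the dense region it ran from 48.1% of DMSO peaks in the group of lowest fold to 69.5% in the highest. In the treated list it was 21.3% at −log10 q of at least 5. The odds ratio therefore cannot be separated from the cut. Outside the dense region, 121 of 166 shared treated peaks (72.9%, interval 65.5 to 79.5%) were at a gene end, but 10 of 284 treated peaks absent from the DMSO list (3.52%, interval 1.70 to 6.38%), against 3.01% placed (permutation of positions, p = 0.689). As 62.0% of DMSO peaks there were at a gene end, splitting treated peaks by overlap with that list puts gene ends into the shared class and takes them out of the other, so the odds ratio of 73.7 between the classes (Fisher's exact test, adjusted p = 2.44e-57) largely restates the split. Inside gene bodies lay 58.2% of DMSO summits, against 49.9% placed (permutation of positions, p = 0.002), a call that was lost when peaks were placed within 1 Mb (p = 0.154). For treated summits it was 47.0%, against 48.2% placed (permutation of positions, p = 0.645), and p = 0.0240, below placement, within 1 Mb. DMSO peaks of highest fold with no treated peak were at Nfib, a transcription factor gene (fold 27.7), Trim8 (27.02), Jun, which encodes an AP-1 subunit (26.8), Cbx3, a heterochromatin protein gene (25.3), Ssbp2 (25.1), Meis2, a homeobox gene (25.1), Dnpep (24.8) and Mepce, a gene for the capping enzyme of 7SK RNA (24.6).

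**Figure D2:**
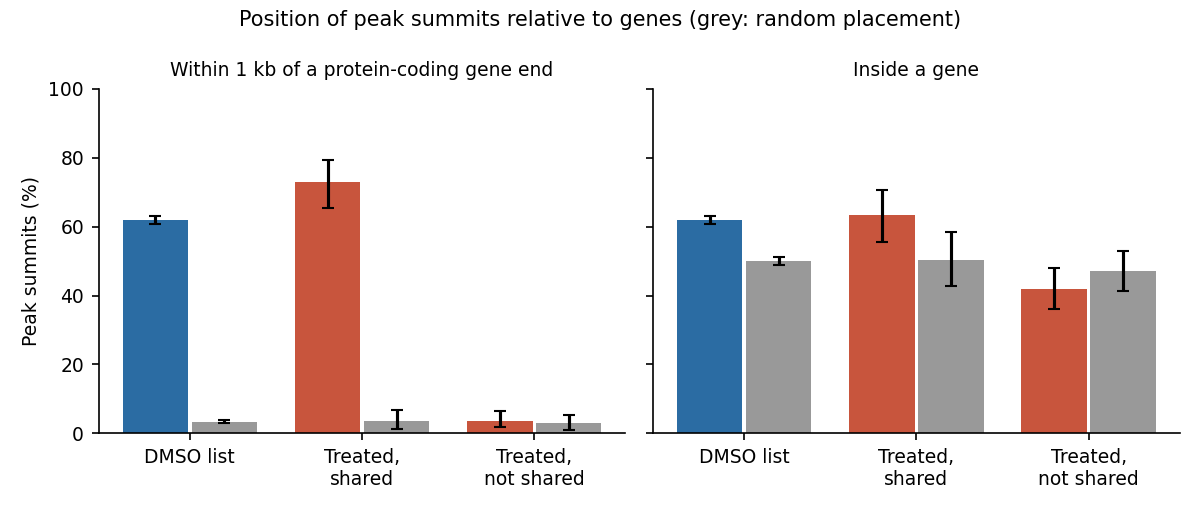
Share of peak summits (%, y axis) within 1 kb of a protein-coding gene end (left) and inside a gene (right), outside the dense region of chromosome 15, for the DMSO list and for treated peaks that do or do not overlap a DMSO peak. Coloured bars have exact 95% intervals, and grey bars are the mean of 1000 random placements with the central 95% of placements. Treated peaks absent from the DMSO list reach 3.52% at gene ends, against 3.01% placed.

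The 291 treated peaks absent from the DMSO list lay inside a gene in 41.6% of cases (interval 35.9 to 47.5%) and at a gene end in 3.44%. Absence from that list does not mean that DMSO cells had no ends there. Peaks of either list had at least 35 pull-down fragments, and these 291 had a median of 43. The DMSO pull-down background was lower (2.88 against 5.14 fragments), so a site of the same enrichment could fall below 35 there. The lowest −log10 q was also higher in the DMSO list (18.5 against 3.38). Among the 291, the peak of highest fold (14.2, −log10 q 34.1) spanned 37699859 to 37701986 on chromosome 13. It lay 77.6 kb from the nearest end of a protein-coding gene, that of the transcription factor gene Rreb1. Next came peaks 8.46 kb from Gata4, a cardiac transcription factor gene (fold 9.61), 6.00 kb from Gdf3, a growth factor gene (9.37), 1.02 kb from Gp9, a platelet glycoprotein gene (9.36), 382 kb from Dach1 (9.21) and 11.2 kb from Tmem130 (9.03). A pair lay 28.02 and 29.05 kb from Gm34768 (folds 8.27 and 8.94), and single peaks lay inside Fhad1 (8.37) and 2.51 kb from Ptgr2, a prostaglandin reductase gene (8.27). Sephs1, a selenophosphate synthetase gene, and Ttll9, a tubulin ligase-like gene, each held 3 treated summits and 0 DMSO summits. The treated summits of each gene lay close together, 12.4, 13.2 and 13.6 kb from a gene end in Sephs1 and 12.7, 13.1 and 13.6 kb in Ttll9. The non-coding genes 0610040F04Rik and 4930402D18Rik held 3 treated summits each, with 1 and 4 DMSO summits. The treated summits in 0610040F04Rik lay 983, 264 and 154 bp from an end of the protein-coding gene Bhlhe40. The treated summits in 4930402D18Rik lay in the dense region of chromosome 15, with folds of 3.26, 3.91 and 3.70.

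Treated peaks absent from the DMSO list often came in close pairs. Outside the dense region, 98 of 284 (34.5%, interval 29.0 to 40.4%) had another such peak within 2 kb, against 0.0754% placed (permutation of positions, p = 0.002). Of the shared treated peaks 22 of 166 (13.3%) had another shared peak as near. Fisher's exact test between the classes gave p = 5.16e-07, which is too small, since it counts both members of a pair as independent. For DMSO peaks the share was 4.93%, but their width seldom leaves room for summits this close. The median distance between the summits of a pair was 868 bp in the treated-only class and 661 bp in shared treated peaks. A pair of this kind lay inside Ccser1, a gene of a common fragile site, with folds of 7.73 and 5.30. The median gap between the peaks of a pair was 452 bp in the treated-only class, 161.5 bp in shared treated peaks and 154 bp in DMSO peaks. Summits lay in the part of the peak nearer the gap in 71.2% (74 of 104), 45.8% (11 of 24) and 88.1% (266 of 302). Whether a pair is 2 sites or 1 site called as 2 peaks was not tested, so peaks are not a count of sites. Within 50 kb of another peak lay 56.1% of DMSO peaks, against 28.1% placed, and 36.5% of treated peaks, against 3.06% placed (permutation of positions, p = 0.002 for both).

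Of the genes of common fragile sites and of break clusters in neural progenitors, which are long, fewer held a summit than placement gave. In the DMSO list, 5 of 30 fragile site genes held a summit, among them Ctnna3 and Tenm3, against 25.6 placed, and 1 of 33 break cluster genes, Nfia, against 26.4 placed (permutation of positions, adjusted p = 0.00280 for both). In the treated list it was 1 of 30, Ccser1, against 7.06 placed (permutation of positions, adjusted p = 0.0350), and 0 of 33, against 5.53 placed (adjusted p = 0.0280). Both treated calls were lost with fewer peaks, at −log10 q of at least 5 (permutation of positions, adjusted p = 0.550) and among peaks at or above the median fold (adjusted p = 0.497). Placement spreads peaks evenly along chromosomes, but 57.2% of DMSO summits lay within 1 kb of a protein-coding gene end, against 3.27% placed. Departures in either direction can thus follow from gene ends and gene length, and placement alone cannot single out these lists. Placement also draws each peak on its own. In the data 36.5% of treated peaks lay within 50 kb of another, against 3.06% placed, and 56.1% of DMSO peaks, against 28.1%. Clustered peaks reach fewer genes, so the placed numbers can be too high and the p-values too small. For 3 lists, more genes than placed held a DMSO summit, each list with adjusted p = 0.00280 by permutation of positions. They were fibroblast genes (10 of 26 against 2.21, such as Fn1, Sparc and Lox of the extracellular matrix), p53 response genes (7 of 23 against 0.965, such as Cdkn1a, a cell cycle inhibitor, and Mdm2, the ligase that degrades p53) and histone genes (13 of 97 against 0.364). Early replicating fragile site genes (5 of 19 against 3.80, permutation of positions, adjusted p = 0.589) and ATR and fork genes (4 of 26 against 1.90, adjusted p = 0.270) did not pass, although with 10 kb on each side 13 ATR and fork genes did (adjusted p = 0.00233), among them Rpa1, Rpa2 and Rpa3, which encode the single-strand binding complex. In the treated list these 5 lists held 1 gene, Actb, which encodes cytoplasmic actin (fold 4.95), and none of the 5 passed.

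Peaks were uneven among chromosomes. In the treated list, chromosome 15 held 3.10 times the number set by its length (58 peaks), chromosome 17 held 2.12 times, and chromosome 8 held 2.05 times, and chromosomes 9 and 12 held 0.177 and 0.187 times (simulated binomial counts, adjusted p at most 0.000180). In the DMSO list, chromosome 15 held 3.299 times (811 peaks), and chromosomes 17, 19 and 11 held 1.88, 1.68 and 1.66 times (simulated binomial counts, adjusted p = 3.50e-05). The X chromosome held 44 treated peaks (8.96%) and 41 DMSO peaks (0.636%), an odds ratio of 15.4 (Fisher's exact test, adjusted p = 2.13e-28). Away from gene ends and the dense region it was 13.8% against 0.975%, an odds ratio of 16.2 (Fisher's exact test, adjusted p = 2.44e-25). By length, X held 0.101 times its number of DMSO peaks (simulated binomial counts, adjusted p = 3.50e-05) and 1.42 times its number of treated peaks (adjusted p = 0.0363). The treated call was lost at −log10 q of at least 5 (1.55 times, simulated binomial counts, adjusted p = 0.0848). With X and Y counted as single copies, X was at 0.192 times (DMSO, simulated binomial counts, adjusted p = 3.00e-05) and 2.70 times (treated, adjusted p = 7.00e-05). The contrast was smaller over the numbers in peak names, where X spanned 272 of 5400 treated numbers (5.04%) and 1060 of 64322 DMSO numbers (1.65%), so it depends on which peaks entered the lists. All 44 treated peaks on X were absent from the DMSO list, a class in which 34.5% outside the dense region had another such peak within 2 kb. The tests by chromosome count each peak as independent, so their p-values are too small.

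**Figure D3:**
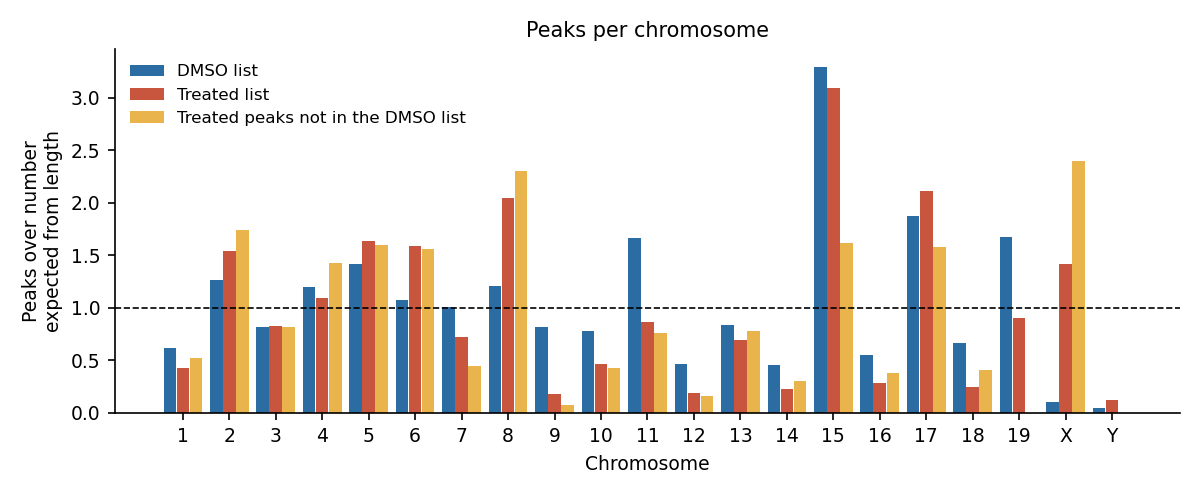
Number of peaks over the number expected from chromosome length (y axis) for each chromosome (x axis), in the DMSO list, the treated list and the treated peaks that overlap no DMSO peak, with a dashed line at 1. Chromosome 15 reaches 3.299 and 3.10 in the whole lists, and X reaches 2.40 in treated peaks that overlap no DMSO peak.

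Much of the excess on chromosome 15 lay in 1 region. From 60000001 to 62300000 (2.3 Mb) lay 506 DMSO peaks and 41 treated peaks, at 220.0 and 17.8 peaks per Mb, against 2.19 and 0.166 per Mb in the rest of the genome. Without the region, chromosome 15 held 0.990 times its number of treated peaks (simulated binomial counts, adjusted p = 1), and 1.35 times its number of DMSO peaks (305 peaks, adjusted p = 3.00e-05). The region holds Myc, a growth-promoting transcription factor gene (61985341 to 61990361), and Pvt1, the non-coding gene beside it (62037986 to 62260215). Beside Myc lay DMSO peaks with folds of 10.2 and 5.81 and a treated peak with a fold of 2.39. Pvt1 held 19 DMSO summits and 1 treated summit. Median input coverage at peaks of the region was 15 fragments in the DMSO list and 16.2 in the treated list, above the genome backgrounds of 2.32 and 2.26. The share of each list in the region was 7.85% (DMSO) and 8.35% (treated, Fisher's exact test, adjusted p = 0.664). Over the numbers in peak names the region spanned 854 DMSO numbers (1.33%) and 1326 treated numbers (24.6%), so the like shares hold for the deposited peaks alone.

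**Figure D4:**
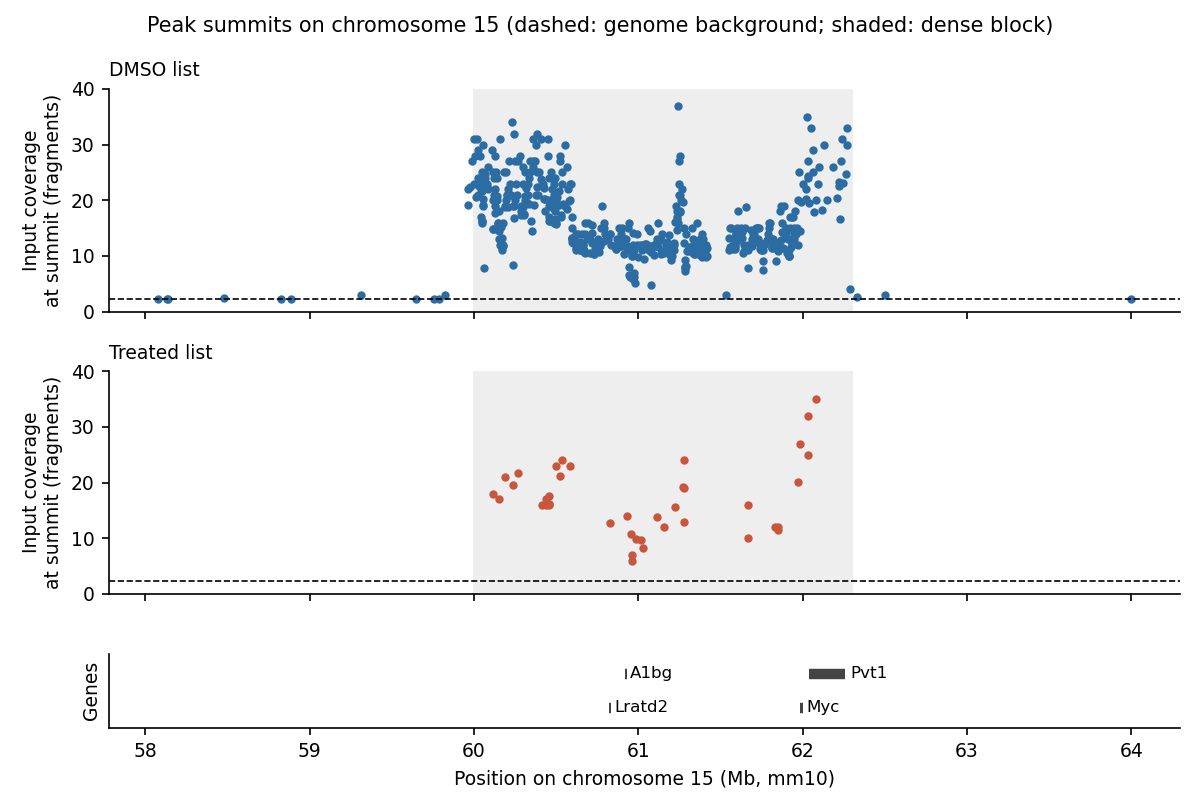
Input coverage at each peak summit (fragments, y axis) along chromosome 15 (Mb, x axis) in the DMSO list (top) and the treated list (middle), with the dense region shaded, the genome background dashed and genes drawn to scale below, widened to 15 kb where shorter. Summits in the region have medians of 15 and 16.2 fragments, and the 18 within 2 Mb on each side in the DMSO list 2.39.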

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

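Every test of an explanation in this part was chosen after the result was seen, except the relation of treated-only peaks to gene ends per Mb. The input libraries, which the comparisons of peaks do not use, showed a signal of their own. Input coverage at peaks in the dense region of chromosome 15 was 6.48 times the genome background in the DMSO list and 7.15 times in the treated list.

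The packing of peaks into this 2.3 Mb was weighed first. The density of gene ends is argued against, since 0.791% of the DMSO peaks there were at a gene end, against 62.0% elsewhere. Extra copies of the region in these cells may account for it, as the lower of the medians was 6.48 times the background. The median of the 18 DMSO peaks within 2 Mb on each side was 1.03 times, but 22.2% of them were at 2 times or more. The treated list had 0 peaks there, so its edge was not seen in both lists. Repeat sites that collect reads cannot be told apart from extra copies, and the input between peaks was not seen. Of the DMSO peaks in the region, 99.6% had an input coverage of at least 2 times the background, which both explanations give. The higher input coverage was present in both conditions. The median fold of DMSO peaks in the region was 4.91, against 19.5 (shared) and 11.2 (in the DMSO list alone) outside it. In the treated list it was 2.76, against 5.18 (shared) and 5.30 (in the treated list alone). Peaks of the region thus had lower folds over the input within each list. As folds were seen at called peaks alone, whether ends differ in frequency per copy stays open.

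The treated list was far shorter. A shallower treated pull-down is argued against by its background coverage, 1.79 times that of the DMSO pull-down. A filter that kept a smaller share of treated calls is argued against if the numbers in peak names count the calls, since the treated list as a whole kept 0.908 times the share that the DMSO list kept, although in the dense region 41 of 1326 treated and 506 of 854 DMSO numbers were kept. A weaker treated signal over which only the strongest DMSO sites stand may account for the shared part, as 10.95% of DMSO peaks in the group of highest fold met a treated peak. Most peaks of that group met none, however. Outside the dense region, DMSO peaks without a treated peak reached a fold of 27.7, above the third quartile of 22.2 for DMSO peaks with one. DMSO fold alone thus did not decide which sites were shared. Whether the treatment spread ends over the genome, lowered them at these sites or a library differed cannot be separated with 1 pooled list per condition.

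Treated peaks were uneven among autosomes. Chromosome copy number of the cell line is a candidate explanation, as peaks over expectation, without the dense region, rose with the share of DMSO peaks whose input coverage was above the background (19 autosomes, Spearman rho = 0.819, permutation p = 7.00e-05, adjusted over 7 relations 0.000490, Pearson r = 0.777, permutation p = 0.000120, adjusted 0.000840). Without chromosomes 5 and 6, the farthest from the median, r was 0.750 and rho 0.792. The density of gene ends stays undecided for the peaks absent from the DMSO list (rho = 0.209, permutation p = 0.388, adjusted 0.388, r = 0.0711, permutation p = 0.773, adjusted 0.773, and r = 0.245 without chromosomes 7 and 11), because rho lay just above the bound of 0.2 set beforehand for excluding it. Chromosomes are not replicate samples, and the input was seen at peak positions alone.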

How the results depend on the processing

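Comparisons without the dense region of chromosome 15, placement within 1 Mb, a DMSO list cut to 491 peaks, neighbours within 2 kb, single copies of X and Y and ends of all genes were chosen after seeing the data. For the main results 65 alternatives were counted as unchanged, but 9 of them left the peaks as they were (the −log10 q of 5 in the DMSO list, and merging), which leaves 56. Those with a test kept direction and side of the threshold. Others are counts without a p-value, where a fall from 15 to 11 treated chromosomes departing from their length counted as unchanged. The 56 also include the gene-end contrast between shared and other treated peaks, which largely restates the split. The overlap ran from 2.44% (at least 50% of both peaks) to 44.2% (peaks within 5 kb), above placement each time. At a −log10 q of at least 5 the treated list fell to 235 peaks and 0 gene lists departed from placement. Among peaks at or above the median fold 3226 DMSO and 250 treated peaks remained by construction, 9 chromosomes departed from their length in the treated list, 0 gene lists did, and chromosome 15 turned to 0.839 times its number. Fewer peaks were tested in each of these. Without the dense region chromosome 15 was at 0.990 in the treated list, and at 1.35 in the DMSO list, still above its length. With placement within 1 Mb the share inside genes lost its call in the DMSO list (58.2%, permutation of positions, p = 0.154) and gained one, below placement, in the treated list (47.0%, p = 0.0240); the cause was not tested. The treated share inside genes, which did not pass, turned from below to above placement among peaks at or above the median fold (50%) and without the dense region (49.8%). Without passing, 4 treated gene lists also turned, fibroblast genes to below placement at or above the median fold (0 genes), and early replicating fragile site (2), ATR and fork (1) and histone genes (5) to above it with 10 kb on each side. No paired analysis was possible because each condition has 1 pooled list without values per sample, and for the same reason no sample was left out in turn. Planned tests of tandem repeats, other sequence features and fold by repeat were not run, as no genome sequence was used here. Both lists hold peaks with at least 35 pull-down fragments, and whether depth or a selection set this was not tested.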

Other observations

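The tests of genes with a summit within 1 kb of an end were chosen after the data were seen, as were the 9 gene families. Of 21887 protein-coding genes, 4272 (19.5%) had a DMSO summit at an end and 150 (0.685%) a treated one. The exact tests of families and lists below count each gene as independent. Since 1 summit counts for every gene with an end within 1 kb, their p-values are too small where members lie in clusters. Histone genes had one more often than other protein-coding genes in the DMSO list (55 of 97, 56.7% against 19.4%, adjusted p = 3.00e-15), as did ATR and fork genes (13 of 26, adjusted p = 0.00107), p53 response genes (11 of 23, adjusted p = 0.00360), fibroblast genes (12 of 26, adjusted p = 0.00360) and genes of ribosomal proteins (33 of 82, 40.2%, adjusted p = 5.10e-05), by Fisher's exact test with Benjamini-Hochberg adjustment. Olfactory receptor genes, used by sensory neurons, had 0 of 1110 by the same exact test (interval up to 0.332%, adjusted p = 5.71e-107), vomeronasal receptor genes 2 of 355 (Vmn1r4 and Vmn2r29, adjusted p = 8.91e-30), keratin genes 1 of 53 (Krt80, adjusted p = 0.000530) and defensin genes 0 of 71 (adjusted p = 1.76e-06). Hox genes (6 of 39), proteasome subunit genes (7 of 40), mitochondrial ribosomal protein genes (18 of 78) and AP-1 genes (4 of 8, Atf3, Jun, Fosl2 and Junb, adjusted p = 0.0755, exact) did not pass. Common fragile site genes, fewer of which held a summit in their body than placed, showed no such difference at their ends (5 of 30, adjusted p = 0.844, Fisher's exact test), and break cluster genes had fewer (1 of 33, Wwox, adjusted p = 0.0216). Of 408 tRNA genes, 88 (21.6%) had a DMSO summit at an end.

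In the treated list olfactory receptor genes had 0 of 1110 (Fisher's exact test, adjusted p = 0.0102), and 2 of 8 AP-1 genes, Fosl2 and Jund, had a summit at an end (adjusted p = 0.0102, exact), a call on 2 genes of a family chosen after peaks had been seen. Of the fixed lists, 2 of 19 early replicating fragile site genes, Myc and Pim1, had one (adjusted p = 0.0394, Fisher's exact test). This call rests on 2 genes, of which Myc lies in the dense region of chromosome 15, and with 10 kb on each side the same genes did not pass against placement (0.437 placed, permutation of positions, adjusted p = 0.199). Of 97 histone genes, 3 had a treated summit at an end, H2ac19, H2az1 and H3c15, which did not pass (Fisher's exact test, adjusted p = 0.117). Pcna, the replication clamp gene, had a summit at an end in both lists (folds 18.0 and 5.16), as did Pim1, a kinase gene (23.4 and 4.87).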
